A study of Arabidopsis thaliana with 3 samples.

How the data were processed

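Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the Arabidopsis MADS-domain proteins PISTILLATA (PI) and APETALA3 (AP3) were bound in young flowers. Both proteins carried a green fluorescent protein (GFP) tag and were precipitated with an anti-GFP antibody. Per the labels, the plants were of the Landsberg erecta background and carried the AP1-GR ap1 cal system, in which dexamethasone lets an AP1 fusion protein start flower development in many meristems at the same time. Plants about 4 weeks old, grown at 20 degrees Celsius, were treated with 10 µM dexamethasone, and tissue was taken 4 days later, at about floral stage 4 to 5. The series has 3 libraries, each the sole library of its group. They are PI-GFP, AP3-GFP and a negative control of the same system without a GFP-tagged factor. Files of the PI and AP3 libraries were analysed here, and values of the control were not analysed here.

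The submitters' processing notes name BWA 0.6.1, SAMtools and the TAIR10 genome build. The peak caller, its threshold and the gene models are not given in the sources used here. Per the labels of the series, bound regions were examined against the negative control, so both lists share 1 control library. The authors deposited a peak list per library with chromosome, start, end, width and position of the maximum, and a score that the file headers call Poisson. The authors also deposited a gene table per library with the largest peak score in 5 windows: 2000 to 3000, 1000 to 2000 and 0 to 1000 bp upstream of a gene, inside the gene, and 0 to 1000 bp downstream. These tables list genes with a peak in a window and no others. A peak is described below by the window that holds its score, and it can extend beyond that window. The score has no fixed range and no stated normalization for library size, so it was used mainly to describe, rank and filter peaks within a list. Between the lists, scores of shared peaks were compared by their order (correlation) and by the rank of the PI to AP3 ratio, and the size of such a ratio is not a measure of relative binding. Numbers of reads were not analysed here, so depth is unknown and a shorter list can reflect lower depth or weaker precipitation as well as fewer bound sites.

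A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The shared count was set against 1000 random placements of the other list on the same chromosomes, one-sided, with the extent of each chromosome taken from the peaks. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error over peaks or genes only. Median scores of shared and unshared peaks, and Spearman and Pearson correlations over shared peaks, were tested with 100000 permutations, two-sided. The smallest p these tests can give is 0.001 for placements and 1e-05 for permutations. The lists of target genes were compared by their overlap, the overlap of independent lists and the odds ratio with a 95% interval. The windows of the gene tables were compared by an exact binomial test on genes with a score in only 1 window of the pair, with Benjamini-Hochberg adjustment over 6 tests. Peaks and genes are not replicates, so every p describes these 2 libraries and not the spread between plants.

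Gene symbols and biotypes came from a RefSeq table of assembly TAIR10.1, matched on locus name, in which 2490 of 2544 PI targets and 2101 of 2146 AP3 targets were found. None of its coordinates were used. A gene was tied to a peak through its chromosome and an identical score, where that combination belonged to 1 peak. It did so for 1422 of 1852 PI peaks and 994 of 1524 AP3 peaks. Where it did not, no position is given for a gene.

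There were 11 gene lists with 188 different genes, fixed before the data were examined. They covered floral organ identity and related MADS-box genes, floral meristem and flowering time, petal and stamen development, carpel development, organ boundary and polarity, TCP growth regulators, the gibberellin pathway, the auxin pathway, the jasmonate, brassinosteroid and cytokinin pathways, photosynthesis and housekeeping. TIP41 and SAND were left out because their loci did not carry these symbols in the reference table. Each list was tested against the other protein-coding genes (27444 in all) with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 22 tests and a threshold of 0.05. Genes were named by a rule fixed at the same time. It took the genes of the 10 highest peaks of each library, all targets in the MADS-box list, up to 4 members with the highest scores from every other list, and the genes of the 5 highest unshared peaks of each library. An item that this rule takes is not reported here.

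Alternatives fixed before the data were examined were a reciprocal overlap of 50%, peak maxima at most 100 bp apart, removal of peaks below the median score, lists of equal length, a narrower gene window and a background of all annotated genes. Added after the data were seen were a null model that moved each peak by 5000 to 50000 bp, the AP3 list without a block of chromosome 1, a reduced assignment of genes to peaks, and a background of transcription factor genes. The reduced assignment ranked the windows, with the inside of the gene first and the farthest upstream window last. For each peak it kept the genes in the first-ranked window that held any. Ties and genes with a score repeated among peaks were all kept, so a peak could still have several genes. The gene tables held a score for listed targets alone, so the planned correlation of scores over all genes and the comparison of list medians with random lists were not run. The planned share of peaks upstream of genes was computed over target genes, by the window with the highest score. Shares of peaks with a CArG box, the DNA motif of MADS-domain proteins, and positions in exons, introns or UTRs needed a genome sequence and annotation that were not used here.

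Simplified forms of the overlap and gene list tests were run on simulated data. With 0%, 30% and 60% of 1852 regions planted as shared, 0.859%, 30.6% and 60.3% were recovered on average, and 1, 20 and 20 of 20 simulations passed the threshold. For a gene list of 20 members among 27444 genes, 6 of 200 simulations without enrichment and 199 of 200 with 8-fold enrichment passed. The overlap simulations used fewer placements than the analysis and peaks placed at random along chromosomes, as in its null model. Those of gene lists tested 1 list without adjustment and drew targets gene by gene. They therefore do not cover clustered peaks, peaks assigned to several genes or the adjusted calls. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.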

Results

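Binding of PI and AP3, the B-class MADS-domain proteins that act together to specify petals and stamens, was mapped by ChIP-seq in flowers of about stage 4 to 5. The PI-GFP list held 1852 peaks with a median width of 335 bp, which covered 707 kb in all. The AP3-GFP list held 1524 peaks with a median width of 257 bp, which covered 438 kb. Scores are the authors' own values. They ranged from 25.3 to 9217 with a median of 88.1 for PI, and from 26.6 to 9926 with a median of 58.6 for AP3. The authors' gene tables listed 2544 targets of PI and 2146 targets of AP3. Each factor had 1 library, so the lists have no replicate check. All positions are on the TAIR10 build.

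The highest peak of each library lay at the gene encoding the tagged protein. In the PI library its score of 9217 was listed 0 to 1000 bp upstream of PI (AT5G20240). This peak spanned chromosome 5, 6827876 to 6831200, and was the widest PI peak at 3325 bp. In the AP3 library the score of 9926 was listed 0 to 1000 bp upstream of AP3 (AT3G54340). That peak spanned chromosome 3, 20120401 to 20122064 (1664 bp). Both peaks were wider than the 1000 bp window that held their scores. Each factor also had a peak at the gene of its partner. The AP3 library had its 17th highest peak at PI (score 1033, width 532 bp), and the PI library its 13th highest at AP3 (score 2038, width 988 bp). At both loci the partner's peak was thus the narrower. The top scores were 2.59 times (PI) and 3.96 times (AP3) the next highest score of the same list. Among 1025 shared peaks, the ratio of PI to AP3 score had rank 4 from the high end at PI and rank 2 from the low end at AP3.

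The C-class gene AGAMOUS (AG, AT4G18960), which specifies stamens and carpels, held the 9th highest PI peak (2298) inside the gene at chromosome 4, 10385937 to 10386865, and the AP3 library had a peak of score 577 there. TEM1 (AT1G25560), a repressor of flowering, had a peak 0 to 1000 bp upstream at chromosome 1, 8983276 to 8984378, with scores of 2315 for PI and 1100 for AP3. Their maxima were at the same base, 8983932. The SEPALLATA gene SEP3 (AT1G24260), which encodes a partner of the B-class proteins, held the 4th highest AP3 peak (1872), 2000 to 3000 bp upstream at chromosome 1, 8598415 to 8599123. PI scored 1551 at that site and had its higher SEP3 peak, of 2141, inside the gene at 8594692 to 8596191. There were 4 sites among the 10 highest peaks of both libraries. 1 of them (2407 for PI and 2507 for AP3) lay inside FRUCT5 (AT1G55120) and 2000 to 3000 bp upstream of IDD7 (AT1G55110), which encodes an indeterminate-domain zinc finger protein. The others lay upstream of PAP2 (AT4G29080), an Aux/IAA gene (2428 and 1285), upstream of ECT6 (AT3G17330; 2324 and 1345) and at AT1G26771 and AT1G26773 (2607 and 1417).

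The remaining high PI peaks lay upstream of AT1G67340 (3560 for PI and 49.0 for AP3, chromosome 1, 25228708 to 25229280), PG2 (AT1G70370; 2299 and 981) and LSH1 (AT5G28490; 2198 and 522). The remaining high AP3 peaks lay upstream of BBX13 (AT1G28050; 457 for PI and 1881 for AP3), a B-box zinc finger gene, of AT5G07620 (720 and 1403), of CCB1 (AT3G26710; 1944 and 1227) and of GRF5. The peak at GRF5 (AT3G13960; 1880 and 1539), a growth-regulating factor gene, lay 2000 to 3000 bp upstream and 0 to 1000 bp downstream of AT3G13950. Several of these peaks also lay in windows of neighboring genes, among them emb1967 at AP3, AT3G17340 at ECT6, AT5G28491 at LSH1 and AT1G24265 at SEP3. Likewise, AT1G28040 and AT1G28060 neighbor BBX13, AT5G07625 and AT5G07630 neighbor AT5G07620, and AT3G26700 neighbors CCB1. All 10 of the highest peaks of either library overlapped a peak of the other.

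The design puts the 2 partners side by side, and the peak sets were compared for the extent to which the proteins occupied the same regions. Of the PI peaks, 1025 of 1852 (55.3%, 95% interval 53.0 to 57.6) overlapped an AP3 peak. Random placement gave 16.0 on average and at most 30, so the overlap was 64.2-fold above it. Of the AP3 peaks, 1059 of 1524 (69.5%, 67.1 to 71.8) overlapped a PI peak, 66.5-fold above random placement. Both p-values were 0.001, the smallest the placements can give. The fold depended on the setting, from 39.6 (PI) and 41.4 (AP3) when peaks of the other list were moved by 5000 to 50000 bp, a null model added after the data were seen, to 215 and 221 with a reciprocal overlap of 50%. For distances, each shared PI peak was paired with the highest-scoring AP3 peak it overlapped. Maxima of these pairs lay a median of 23 bp apart (quartiles 4 and 66), and 690 of 1025 pairs (67.3%, 64.4 to 70.2) lay within 50 bp. The lists share 1 negative control, so part of the overlap may come from it. Neither null model kept peaks at like positions relative to genes, so the fold also includes any preference for such positions common to both lists.

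Sharing rose with the score. In the lowest score decile, 18.8% of PI peaks (13.5 to 25.2) and 28.8% of AP3 peaks (21.7 to 36.6) were shared. In the highest decile these shares were 95.7% (91.7 to 98.1) and 99.3% (96.4 to 100). Of the 100 highest peaks, 99 for PI and 100 for AP3 were shared. The median PI score was 140 at shared and 55.7 at unshared peaks (difference 84.1), and the median AP3 score was 81.3 and 38.01 (difference 43.3). Each difference had p = 1e-05 in the permutation test, the smallest it can give.

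**Figure D1:**
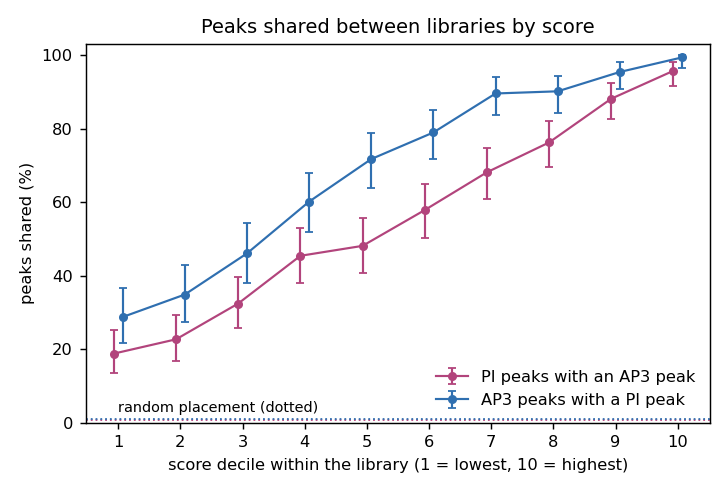
Share of peaks that overlapped a peak of the other library (percent, y axis) by score decile within each library (x axis), with PI in magenta and AP3 in blue. Error bars are Clopper-Pearson 95% intervals and dotted lines the mean of random placements; the share climbs from 18.8% to 95.7% for PI and from 28.8% to 99.3% for AP3.

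The order of scores was alike in the libraries. Each of the 1025 shared PI peaks was paired with the highest-scoring AP3 peak it overlapped, and an AP3 peak could be used more than once. Across these pairs, Spearman's rho was 0.713 and Pearson's r on log2 scores 0.756, each with permutation p = 1e-05, the smallest possible. Without the 2 peaks farthest from the median PI score, r was 0.761. These are correlations across peaks, which are not independent replicates.

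**Figure D2:**
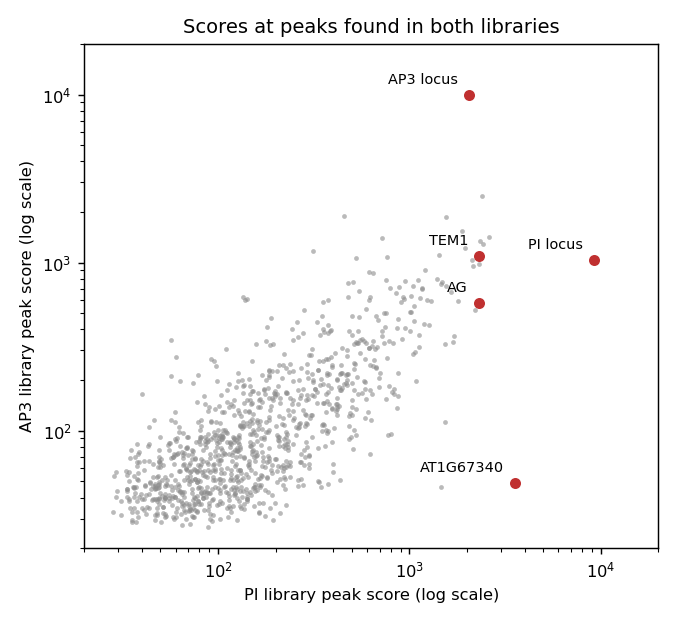
Authors' score of each of the 1025 shared PI peaks (x axis, log scale) and of the highest-scoring AP3 peak it overlapped (y axis, log scale), 1 gray point per PI peak, with 5 peaks named in the text in red. Scores rise together (rho 0.713), while the PI and AP3 loci lie to the right of and above the other points and AT1G67340 far below them.

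The highest PI peak without an AP3 peak lay 1000 to 2000 bp upstream of PHAVOLUTA (PHV, AT1G30490), a class III homeodomain-leucine zipper gene of adaxial identity, at chromosome 1, 10801875 to 10802361 (score 727, rank 80). PHV was still an AP3 target, through a peak of score 99.3 on its downstream side at 10795028 to 10795341. A PI peak overlapped that downstream peak, so both factors had a peak there. The next unshared PI peaks lay near VAMP713, APT5 and UAP56a (611, chromosome 5, 3550111 to 3550590), near ABF1 and AT1G49715 (540, chromosome 1, 18398874 to 18399249), where ABF1 is a bZIP gene of abscisic acid responses, near SAMC1, AT4G39470 and CYP96A9 (513, chromosome 4, 18361490 to 18361928) and near NIK3 and ACLA-2 (491, chromosome 1, 22387647 to 22388131). The highest AP3 peak without a PI peak lay upstream of BIG BROTHER (BB, AT3G63530) and beside AT3G63540, of which BB encodes a ubiquitin ligase that limits floral organ size, at chromosome 3, 23458610 to 23459323 (score 351, rank 101). The others lay upstream of AT1G27550 (250, chromosome 1, 9570231 to 9571684), in a region with no listed gene (237, chromosome 1, 15081950 to 15082299), upstream of AT3G05620 and AT3G05625 (207, chromosome 3, 1631660 to 1632087) and upstream of AT2G37100, AT2G37110 and IRX9 (173, chromosome 2, 15590748 to 15591125), the last a xylan synthesis gene. The peak at AT1G27550 belonged to a block of 13 AP3 peaks with no PI peak. A region missing from a list may have fallen under the authors' threshold.

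Most target genes of each factor were also targets of the other. Among protein-coding genes, 1460 were targets of both, 926 of PI alone and 532 of AP3 alone. Independent lists of these sizes would share 173, so the overlap was 8.43 times that, with an odds ratio of 72.7 (95% interval 64.5 to 81.9). It was 15.3 times the expected number (odds ratio 116) with windows from 1000 bp upstream to the gene end, and 17.8 times (odds ratio 209) without peaks below the median score. The shared genes made up 61.2% of PI targets (59.2 to 63.2) and 73.3% of AP3 targets (71.3 to 75.2). Counting genes of any type, 1558 were in both lists, and 1039 of them had a positioned highest peak in each. For 986 of these 1039 (94.9%, 93.4 to 96.2), the 2 peaks overlapped. A repeated score left a gene without a position, and the most common scores, 33.4 for PI and 30.5 for AP3, were near the lowest. Genes with weak peaks, which were shared less often, may therefore be missing from this share. A peak can be assigned to several neighboring genes, so genes were not independent of each other. With the reduced assignment of genes to peaks, a setting added after the data were seen, the shares fell to 56.1% of PI and 64.1% of AP3 targets. The overlap was then 9.85 times the expected number, with a lower odds ratio of 57.1 (50.4 to 64.7). This setting still held 1563 protein-coding AP3 targets for 1524 AP3 peaks, so it lessened the dependence between genes without removing it.

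Peaks were found more often in the 1000 bp upstream of target genes than farther upstream. The highest score lay 0 to 1000 bp upstream for 30.8% of PI targets (29.0 to 32.6) and 27.5% of AP3 targets (25.6 to 29.4), as at PI, AP3 and TEM1. In contrast, 15.0% and 14.5% had it 1000 to 2000 bp upstream, and 17.9% and 15.8% had it 2000 to 3000 bp upstream, as at SOC1 and SVP. It lay inside the gene for 16.9% and 20.8%, as at AG and AP1, and downstream for 19.4% and 21.3%, as at FD. With genes scored in both windows set aside, 831 PI targets had a peak 0 to 1000 bp and 400 had one 1000 to 2000 bp upstream (adjusted exact p = 1.88e-34, exact binomial test). For AP3 these counts were 603 and 324 (adjusted exact p = 5.34e-20). The inside window varies with gene length and was not compared with the others.

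**Figure D3:**
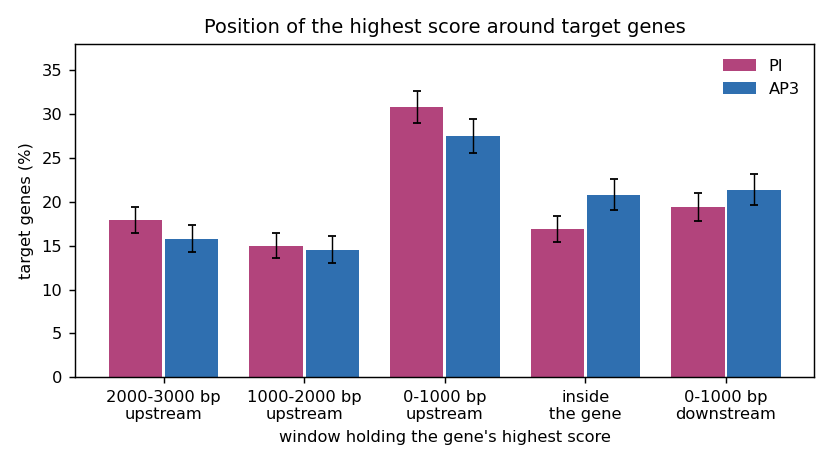
Percent of target genes (y axis) whose highest peak score lay in each window of the authors' gene tables (x axis), for 2544 PI targets (magenta) and 2146 AP3 targets (blue). Error bars are Clopper-Pearson 95% intervals; the 0 to 1000 bp upstream window is the tallest in both libraries, at 30.8% and 27.5%.

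Floral organ identity and related MADS-box genes were the list with the highest share of targets. PI was present at 17 of 22 members (77.3%, 54.6 to 92.2, adjusted exact p = 3.33e-13, Fisher's exact test) and AP3 at 15 (68.2%, 45.1 to 86.1, adjusted exact p = 5.97e-12), against 8.64% and 7.21% of other protein-coding genes. All 15 AP3 targets in the list were PI targets too. SEP4 (PI score 90.6, chromosome 2, 1130000 to 1130379) and AGL42 (181, chromosome 5, 24965549 to 24966069) were listed for PI and not for AP3. SEP1, SHP1, STK, AGL13 and AGL24 were listed for neither.

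Within this list, the meristem identity gene AP1 (AT1G69120) had a peak inside the gene at chromosome 1, 25985680 to 25987021, with scores of 870 for PI and 219 for AP3. Its close relative CAL (AT1G26310) scored 272 and 64.7, with the PI peak 0 to 1000 bp upstream at chromosome 1, 9103199 to 9103954. FUL (AT5G60910), a gene of inflorescence and fruit development, scored 528 and 1062 inside the gene at chromosome 5, 24505006 to 24505794. SEP2 (AT3G02310) scored 542 and 331 at chromosome 3, 467653 to 468038. SHP2 (AT2G42830), a carpel and fruit gene, scored 288 and 123 at chromosome 2, 17819684 to 17820102, and AGL6 (AT2G45650) scored 370 and 96.8 at chromosome 2, 18801534 to 18802215. Genes that control flowering time were also bound. The flowering promoter SOC1 (AT2G45660) scored 1199 and 902 at chromosome 2, 18812688 to 18813664, and the repressor SVP (AT2G22540) scored 1051 and 447 at chromosome 2, 9577390 to 9577888. The repressors AGL15 (AT5G13790, 1051 and 554, chromosome 5, 4450766 to 4451964) and AGL18 (AT3G57390, 867 and 161, chromosome 3, 21233322 to 21233894) had peaks 0 to 1000 bp upstream. FLC (AT5G10140) scored 150 and 258, with the AP3 peak at chromosome 5, 3181891 to 3182313.

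**Figure D4:**
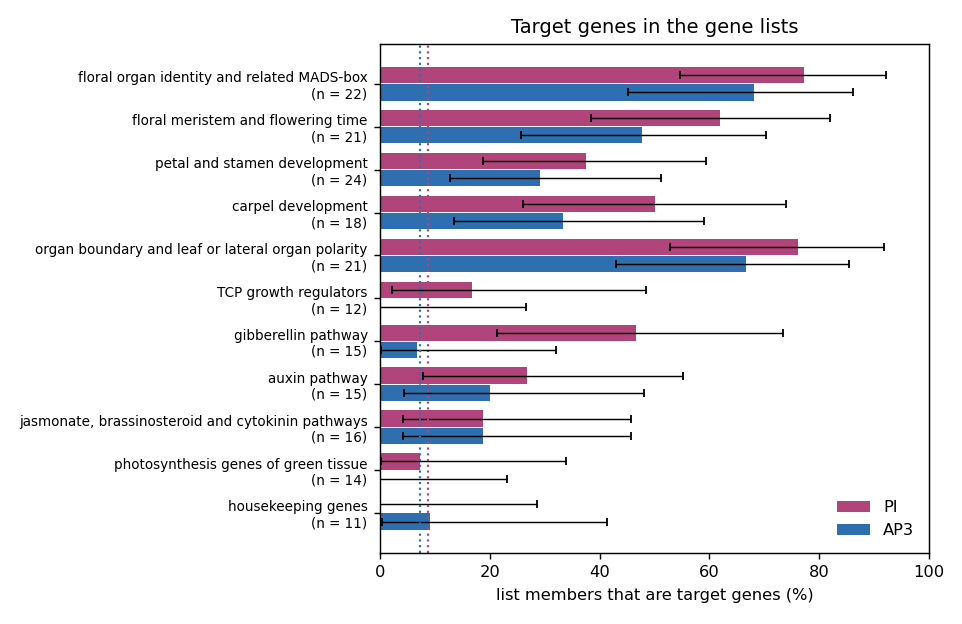
Percent of the members of each gene list that were targets (x axis) for PI (magenta bars) and AP3 (blue bars), with the number of members beside each list name. Error bars are Clopper-Pearson 95% intervals and dotted lines the mean share among other protein-coding genes; the MADS-box list (77.3% and 68.2%) and the boundary and polarity list (76.2% and 66.7%) reach farthest.

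Organ boundary and polarity genes were targets nearly as often, with 16 of 21 for PI (76.2%, 52.8 to 91.8, adjusted exact p = 1.49e-12) and 14 for AP3 (66.7%, 43.0 to 85.4, adjusted exact p = 4.24e-11). PHV is described above. ASYMMETRIC LEAVES1 (AS1, AT2G37630), a MYB gene of leaf and organ polarity, scored 568 for PI and 352 for AP3 at chromosome 2, 15784191 to 15784680. BOP1 (AT3G57130), a regulator of organ boundaries, scored 457 and 190 at chromosome 3, 21144631 to 21145246. LOF1 (AT1G26780), another boundary gene, scored 446 and 179 at chromosome 1, 9269629 to 9270281.

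Floral meristem and flowering time genes were targets in 13 of 21 cases for PI (61.9%, 38.4 to 81.9, adjusted exact p = 7.22e-09) and 10 for AP3 (47.6%, 25.7 to 70.2, adjusted exact p = 2.44e-06). FD (AT4G35900), the bZIP partner of the florigen FT, had a broad peak on its downstream side at chromosome 4, 17005613 to 17007285, with scores of 2133 for PI and 1041 for AP3. ATH1 (AT4G32980), a homeodomain gene, scored 1085 and 198 at chromosome 4, 15917947 to 15919358. The AP2-type genes TOE3 (AT5G67180, 434 for PI at chromosome 5, 26806622 to 26807089, and 141 for AP3) and AP2 (AT4G36920, 426 and 181, chromosome 4, 17398685 to 17399127) were targets of both. Chosen after the values were seen, UFO (AT1G30950), an F-box gene needed for B-class gene expression, scored 379 and 217 at chromosome 1, 11033693 to 11034144. SUPERMAN (SUP, AT3G23130), which limits B-class gene expression at the carpel boundary, scored 201 for PI at chromosome 3, 8241127 to 8241585, and was not listed for AP3.

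Carpel development genes were targets in 9 of 18 cases for PI (50%, 26.02 to 74.0, adjusted exact p = 2.07e-05) and 6 for AP3 (33.3%, 13.3 to 59.0, adjusted exact p = 0.00252). They included the auxin response factor gene ETT (AT2G33860, 830 and 177, chromosome 2, 14331064 to 14331662), the YABBY gene CRC (AT1G69180, 502 and 153, chromosome 1, 26011540 to 26012015), HEC1 (AT5G67060, 328 and 170, chromosome 5, 26765380 to 26765848) and NTT (AT3G57670, 268 and 157, chromosome 3, 21371765 to 21372220). Petal and stamen development genes were targets in 9 of 24 cases for PI (37.5%, 18.8 to 59.4, adjusted exact p = 0.000300) and 7 for AP3 (29.2%, 12.6 to 51.1, adjusted exact p = 0.00252). They included the anther receptor kinase gene EMS1 (AT5G07280, 830 and 164, chromosome 5, 2283964 to 2284457), ARF6 (AT1G30330, 440 and 175, chromosome 1, 10692870 to 10693467), SPL8 (AT1G02065, 356 and 259, chromosome 1, 365252 to 365766) and the sporogenesis gene SPL (AT4G27330, 264 and 109, with the AP3 peak at chromosome 4, 13685955 to 13686300). With windows limited to 1000 bp upstream to the gene end, fewer genes were targets and the AP3 calls were lost, with 3 petal and stamen genes (odds ratio 3.58, 1.07 to 12.04, against 5.28, 2.19 to 12.7, adjusted exact p = 0.138) and 3 carpel genes (odds ratio 5.02, 1.45 to 17.4, against 6.405, 2.40 to 17.1, adjusted exact p = 0.0732). Against transcription factor genes as background, the petal and stamen calls were lost for PI (odds ratio 2.50, adjusted exact p = 0.0750) and AP3 (2.76, adjusted exact p = 0.0715), and the carpel call for AP3 (3.34, adjusted exact p = 0.0606).

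Gibberellin pathway genes were targets of PI in 7 of 15 cases (46.7%, 21.3 to 73.4, adjusted exact p = 3.13e-04) and of AP3 in 1 (6.67%, 0.169 to 31.9, adjusted exact p = 1). The receptor gene GID1B (AT3G63010) was a target of both, with scores of 221 for PI at chromosome 3, 23291012 to 23291825, and 108 for AP3. PI peaks lay near the DELLA repressor genes RGA (AT2G01570, 118, chromosome 2, 258962 to 259295) and RGL2 (AT3G03450; 75.9) and near GA2OX1 (AT1G78440; 56.9), a gene of gibberellin breakdown. The difference between the factors (6 genes for PI alone against 0 for AP3 alone) did not pass its test (exact p = 0.0920, adjusted exact p = 0.767 over 11 lists), nor did that of any other list. The PI call was lost, with 2 targets left and the odds ratio down from 9.21 (3.34 to 25.4), with windows limited to 1000 bp upstream to the gene end (3.24, 0.730 to 14.4, adjusted exact p = 0.248) and without peaks below the median score (3.41, 0.769 to 15.1, adjusted exact p = 0.229). Against transcription factor genes as background it was kept narrowly, with an odds ratio of 3.65 (1.30 to 10.2, adjusted exact p = 0.0453, Fisher's exact test).

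The other lists did not pass the test. Auxin pathway genes were targets in 4 of 15 cases for PI (adjusted exact p = 0.0655) and 3 for AP3 (adjusted exact p = 0.153). PI scored 162 at MP (AT1G19850, chromosome 1, 6884404 to 6884774), 142 at the auxin synthesis gene YUC4 (AT5G11320, chromosome 5, 3613192 to 3613782) and 43.5 at AXR3. AP3 scored 38.1 at YUC4. The PI call for auxin genes was gained with all annotated genes as background (adjusted exact p = 0.0259) and with the reduced assignment of genes to peaks (adjusted exact p = 0.0251). Jasmonate, brassinosteroid and cytokinin genes were targets in 3 of 16 cases for each factor (adjusted exact p = 0.231 for PI and 0.165 for AP3). These were the brassinosteroid regulator BZR1 (AT1G75080, 375 and 382, chromosome 1, 28183495 to 28184192), the cytokinin response regulator ARR7 (AT1G19050, 323 and 177, chromosome 1, 6579284 to 6579691) and the receptor gene BRI1 (AT4G39400; 52.3 and 38.9). TCP growth regulators were targets in 2 of 12 cases for PI, TCP24 (77.3) and BRC1 (34.1), and 0 for AP3 (adjusted exact p = 0.386 and 1). In the wider TCP family, recognized by symbol after the data were seen, 6 of 22 genes were PI targets (27.3%, adjusted exact p = 0.0410) and 3 were AP3 targets (adjusted exact p = 0.367). Among the comparison lists, PSBO2 (PI score 33.4) was the sole target of 14 photosynthesis genes and UBQ10 (AP3 score 48.3) the sole target of 11 housekeeping genes.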

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

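With 1 library per factor, no paired analysis was possible because no group has a second library, and no replicate could be left out. Of 35 alternatives to the 10 main results, 27 counted as unchanged, 8 moved the value and none reversed it. For the gene lists, a number of called lists within 1.5-fold of the main number counted as unchanged, although single calls could differ. Shared PI peaks ranged from 42.4% to 62.9% and shared AP3 peaks from 51.6% to 77.0%, each at the smallest p the placements allow. Moving each peak by 5000 to 50000 bp, a test added after the data were seen, raised the chance overlap to 25.9 PI peaks and 25.5 AP3 peaks. Without peaks below the median score, the median difference between shared and unshared peaks was 130.2 for PI and 70.1 for AP3, and the highest score lay within 3000 bp upstream for 66.9% of PI and 64.5% of AP3 targets (63.7% and 57.8% with all peaks). Limiting that window to 1000 bp gave 30.8% and 27.5%, by construction. AP3 had 5 lists past the threshold, and 3 both with windows from 1000 bp upstream to the gene end and with the transcription factor background, which was added after the data were seen; the cause was not tested. PI had 6 lists, and either 5 or 7 under each alternative, so each changed at least 1 PI call. Of 110 tests of single lists under alternatives, 7 lost and 2 gained a call. Alternatives that needed the genome sequence, strand or annotation were not run: CArG box shares, placement by annotation category, peak centers, own gene assignment within 3000 bp and nearest gene. Alternatives for the correlation over all genes were not run either. Depth is unknown and limits what the absence of a weak peak can show.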

Other observations

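The tests of gene families, of the loci of the tagged proteins, of the chromosome 1 block and of the transcription factor background were all chosen after the data were seen. Among 26 families recognized by gene symbols, 10 had a raised share of PI targets and 4 a raised share of AP3 targets after adjustment over 52 Fisher tests, and 0 had a lowered share. Indeterminate-domain (IDD) zinc finger genes led for PI, with 8 of 12 members (66.7%, 34.9 to 90.1, adjusted exact p = 6.04e-05) against 5 for AP3 (41.7%, 15.2 to 72.3, adjusted exact p = 0.00893). Besides IDD7, whose peak lay inside FRUCT5, they included IDD4 (372 for PI and 149 for AP3), IDD1 (293 and 249) and IDD5 (208 and 122). SQUAMOSA PROMOTER BINDING PROTEIN-LIKE genes, several of which promote flowering, were targets in 7 of 18 cases for PI (adjusted exact p = 0.00651) and 5 for AP3 (adjusted exact p = 0.0365), with SPL8 (356 and 259), SPL9 (280 and 62.4) and SPL2 (182 and 70.6). Of the KNAT homeobox genes, which hold meristem regulators, 4 of 7 were targets of each factor (adjusted exact p = 0.0105 for PI and 0.00843 for AP3), 3 of which are also in the boundary and polarity list. AGAMOUS-LIKE genes, which overlap the MADS-box list, were targets in 23 of 98 cases for PI (adjusted exact p = 2.24e-04) and 20 for AP3 (adjusted exact p = 3.66e-04). The families raised for PI also took in HB homeobox genes (11 of 47, adjusted exact p = 0.0112), WOX genes (5 of 14, adjusted exact p = 0.0264), TCP genes (6 of 22, adjusted exact p = 0.0410) and BLH genes (4 of 11, adjusted exact p = 0.0457). These families are not separate, since HB-3 and WOX13 counted as both HB and WOX targets, and PHV and PHB are HB genes that are also in the boundary and polarity list. For AP3 the counts of HB, WOX, TCP and BLH targets were 6, 2, 3 and 2 (adjusted exact p = 0.304, 0.440, 0.367 and 0.357). TCP targets of both factors were TCP9 (102.9 for PI and 93.1 for AP3), TCP12 (148 and 58.3) and TCP20 (125 and 87.7).

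CLE peptide genes were targets in 7 of 30 cases for PI (adjusted exact p = 0.0472) and 6 for AP3 (adjusted exact p = 0.0619), with CLE42 (1008 for PI and 392 for AP3) and CLE17 (927 and 625) highest. Aux/IAA genes, which encode repressors of auxin responses, were PI targets in 9 of 32 cases (28.1%, adjusted exact p = 0.00919) and AP3 targets in 4 (12.5%, adjusted exact p = 0.289), and the difference between the factors was not tested. PAP2 (2428 and 1285) led this group, which also took in MP through a synonym. MYB (19 of 125 for PI, adjusted exact p = 0.0546), NAC (13 of 100, adjusted exact p = 0.304) and WRKY genes (9 of 72, adjusted exact p = 0.442) did not pass. Cytochrome P450 genes were PI targets in 19 of 250 cases (7.60%, adjusted exact p = 0.788).

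The gene encoding each tagged protein held the highest score of its own library. Transgene copies alone were predicted, after the ranks were seen, to leave the locus weak or missing in the other library. PI ranked 17 of 1524 AP3 peaks and AP3 ranked 13 of 1852 PI peaks, so each locus also had a high peak for the partner. These ranks cannot decide whether construct copies produced the top score, since that score comes from the protein's own library. Whether copies of the tagged construct add to the score cannot be told apart from stronger binding of each protein at its own gene. The PI to AP3 score ratio at PI was the 4th highest of 1025 shared peaks (log2 3.16, median 0.68) and that at AP3 was rank 2 from the low end (log2 -2.28), but these ratios contain the top scores that prompted the question and so decide nothing.

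A block of chromosome 1 from 9567617 to 9591376 held 13 AP3 peaks and 0 PI peaks, with scores of 27.4 to 250, over AT1G27540, AT1G27550, AT1G27570, AT1G27580 and AT1G27590. In 1000 permutations of which AP3 peaks were shared, at most 10 AP3-only peaks lay in 25000 bp (p = 0.001, the smallest they can give). The permutations counted neighboring peaks as separate, though these may be pieces of 1 enriched stretch, and sharing also depended on score. This p may therefore overstate the evidence against chance clustering. Peaks of the block were wider than other AP3-only peaks (median 330 against 144 bp) also at like score, by 0.63 on the log2 scale (permutation p = 0.0051). The width test also counted the block's peaks as separate, and the block was picked as the densest AP3-only stretch. Its p may therefore overstate the evidence too. A difference in DNA amount between the AP3-GFP line and the control is a hypothesis these widths fit without excluding broad binding. Without the block, 70.1% of AP3 peaks were shared.

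The excess of targets in the floral lists was set against a general excess of transcription factor genes. Of 762 genes in 19 transcription factor families, 148 were PI targets (19.4% against 8.39% of other genes) and 100 were AP3 targets (13.1% against 7.09%). Against this background, the MADS-box list still held more targets (adjusted exact p = 5.63e-08 for PI and 5.63e-08 for AP3), as did the boundary and polarity list (adjusted exact p = 1.40e-07 and 1.23e-07). An excess of the size seen in these 762 genes, recognized by symbol, therefore does not account for the whole of these lists. It may account for part of them, since the MADS-box odds ratio fell from 36.0 to 15.5 for PI and from 27.6 to 15.9 for AP3. The boundary and polarity odds ratio fell from 33.8 to 14.2 and from 25.7 to 14.5. The petal and stamen odds ratio went from 6.32 (2.76 to 14.5) to 2.50 (1.07 to 5.82) for PI and from 5.28 (2.19 to 12.7) to 2.76 (1.11 to 6.82) for AP3 (adjusted exact p = 0.0750 and 0.0715). Lists were drawn up from known regulators of flower development, so a hypothesis of preferred binding at floral regulators stays untested beyond these genes.

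Among peaks singled out after their values were seen, AT1G67340 came first. There the score ratio of PI to AP3 was the highest of all shared peaks (3560 against 49.0), with maxima 101 bp apart. COB, next to FUL, followed with 1468 against 45.9 and maxima 143 bp apart. The lowest ratio (56.5 against 348) was at a peak in the windows of AT4G25280, 0 to 1000 bp upstream, AT4G25290, on its downstream side, and OTP70, 2000 to 3000 bp upstream.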
